A study of Mus musculus with 9 samples.

How the data were processed

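Embryonic lateral cortex of C57BL/6 mice was dissociated with papain at embryonic day 14.5 after removal of meninges and ganglionic eminences, and cells were sorted by red and green fluorescence, per the labels' protocols. Poly-A RNA was extracted from pools of sorted cells of several embryos of different litters and made into strand-specific libraries. The 9 libraries form 3 groups of 3: proliferating progenitors, differentiating progenitors and neurons. The titles name a red protein for the Btg2 gate, while the genotype label names green for both reporters, and the groups here follow the titles and the cell type labels.

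Per the submitters' processing notes, CASAVA 1.8.0, BWA, bedtools 2.11, DESeq 1.8.1 and build mm9 were used. Which tool did which step is not given in the sources used here, nor is the strand setting of the counting. The deposited table holds a normalised score per gene and library, in normalised read counts that are whole numbers, for 21210 genes of Ensembl version 61 per the file headers. From the values, these look like read counts divided by a size factor per library and rounded. The authors also deposited folds as the ratio of group means, with an adjusted p-value for each comparison, and the gene length in bases as another column. The method of their adjustment is not given in the sources used here.

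The size of 1 read in each library was estimated from which small whole numbers occur, and gave 12652683 to 27581720 reads per library. These estimates are not exact, so no count model was fitted. Tests used limma 3.58.1 in R 4.3.3 with an intensity trend on log2(value + 1), all 9 libraries in 1 fit with 3 group means and 6 residual degrees of freedom. Genes with a value of at least 10 in at least 3 libraries were tested, 15828 in all, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. A gene was called highest or lowest in differentiating progenitors when it passed both comparisons with that group in the same direction. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 did the rest. On simulated data, with replicate pairing not tested, the fit recovered 49.3%, 53.7% and 59.7% of genes changed 1.5-fold, in the order of the comparisons. It recovered 89.6%, 91% and 83.6% at 2-fold and 100% at 4-fold, with 4.8%, 4.7% and 5.8% false calls. A simulated list with raised genes was called and 0 of the other lists.

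Gene types came from GENCODE release M21, which matched 93.8% of the genes by identifier and 563 more by symbol, and left 757 unmatched. They made 1732 genes long non-coding and 15884 protein-coding. Shares of changed long non-coding and protein-coding genes were compared by an exact conditional test within 10 deciles of mean value. The comparisons, tests, 30 gene lists, naming rule and most alternatives were chosen before the data were examined. Design notes then foresaw a count model for counts and limma for normalised values, and the values decided for limma.

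The lists hold markers of radial glia, intermediate progenitors, pan-neuronal genes, deep and upper layers, interneurons, Cajal-Retzius cells, microglia, endothelial and mural cells, red blood cells, meninges and the oligodendrocyte lineage. Others hold G1/S, G2/M, CDK inhibitor, Notch, Wnt, FGF and Hedgehog, axon guidance, synaptic, ion channel, progenitor-type and neuron-type BAF, DNA methylation and polycomb, RNA-binding, glycolysis, cholesterol synthesis and immediate early genes. The last hold known long non-coding RNAs and those recalled from the study. Each was tested with camera at a preset correlation of 0.01, adjusted over 90 tests, and again with an estimated correlation and with fry, which asks only whether a list's genes move 1 way on balance.

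Genes are named by a rule: Btg2 and Tubb3 first, then per comparison the 8 called genes with the largest rise and the 8 with the largest fall whose replicates do not overlap and whose higher group mean is at least 10. The rule adds 4 long non-coding genes per direction with a mean of at least 2, the 8 with the largest changes highest and lowest in differentiating progenitors, up to 4 members per list with the smallest adjusted p, and all recalled long non-coding RNAs. Some of these are left out of the text, and some members of counts are not reported here. Where members of a list are named beyond this rule, without values of their own, they complete a count or a direction and were chosen after their values were seen.

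Equal replicate numbers were tested for pairing: after removal of group means, all 9 pairs of equal number correlated (r from 0.507 to 0.767 across genes), and other pairs lay between -0.64 and 0.428. A fit with replicate number as a block, with 4 residual degrees of freedom, is therefore given beside the totals, where it changes a camera call of a list in the text, and where it moves a member count in the text by over 1.5 times and more than 1 gene. Member counts are otherwise without the block. Further alternatives were other pseudocounts, filters and samples, leaving out each library, and, chosen after seeing the data, total-sum and upper-quartile scaling, replicates 2 and 3 alone and limma-voom on estimated reads. No library was left out of the main values.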

Results

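Poly-A RNA was sequenced strand-specifically from 9 pools of cells sorted from the lateral cortex of C57BL/6 mouse embryos at embryonic day 14.5, per the labels' protocols. A red reporter of Btg2, a gene switched on in progenitors that go on to make neurons, and a green reporter of Tubb3, a neuronal beta-tubulin, set the gates. Cells negative for red were the proliferating progenitors, red cells the differentiating progenitors, and green cells the neurons, with 3 libraries each. The series asks which transcripts, long non-coding RNAs among them, change as progenitors commit to neurogenesis. Values are normalised read counts for 21210 genes as the authors deposited them, and 15828 genes passed the filter on low values.

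Normalised totals were 17531558, 18201880 and 17600981 in libraries 1, 2 and 3 of proliferating progenitors. They were 18420135, 19077173 and 18608105 in differentiating progenitors and 21598907, 22076409 and 21442620 in neurons. The smallest steps between low values put the reads behind these totals near 12652683, 20210837 and 21490819 in proliferating progenitors. The estimates were 15046671, 23604520 and 18887642 in differentiating progenitors and 18288660, 27581720 and 21340187 in neurons. Group values below are means ± SD of normalised read counts over 3 libraries (n = 3), log2 changes are given ± SE, and adjusted p-values of genes come from limma. The median SE of a log2 change was 0.18.

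The genes behind the sort check the labels and are no findings. Btg2 stood at 8952, 7032 and 9336 in the proliferating progenitor libraries, at 14022, 14635 and 19983 in the differentiating progenitor libraries and at 3299, 2645 and 3390 in the neuron libraries. Tubb3 stood at 2511, 1557 and 1158, then at 10937, 13097 and 9711, then at 50230, 48666 and 39932 in the same order. Each library lay on the side that its label requires. Principal component 1 held 75.1% of the variance and ordered the groups, and principal component 2 held 11.6% and set replicate 1 of every group apart from replicates 2 and 3. Processed pseudogenes, intron-less copies of expressed genes, took 2.40%, 2.22% and 1.70% of the total in the replicate 1 libraries of proliferating progenitors, differentiating progenitors and neurons, against 0.451% to 0.656% in the other 6 libraries. Because replicate 1 of every group shares this, the totals of each comparison and the list tests were also made from replicates 2 and 3 alone, an alternative chosen after seeing the data.

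**Figure D1:**
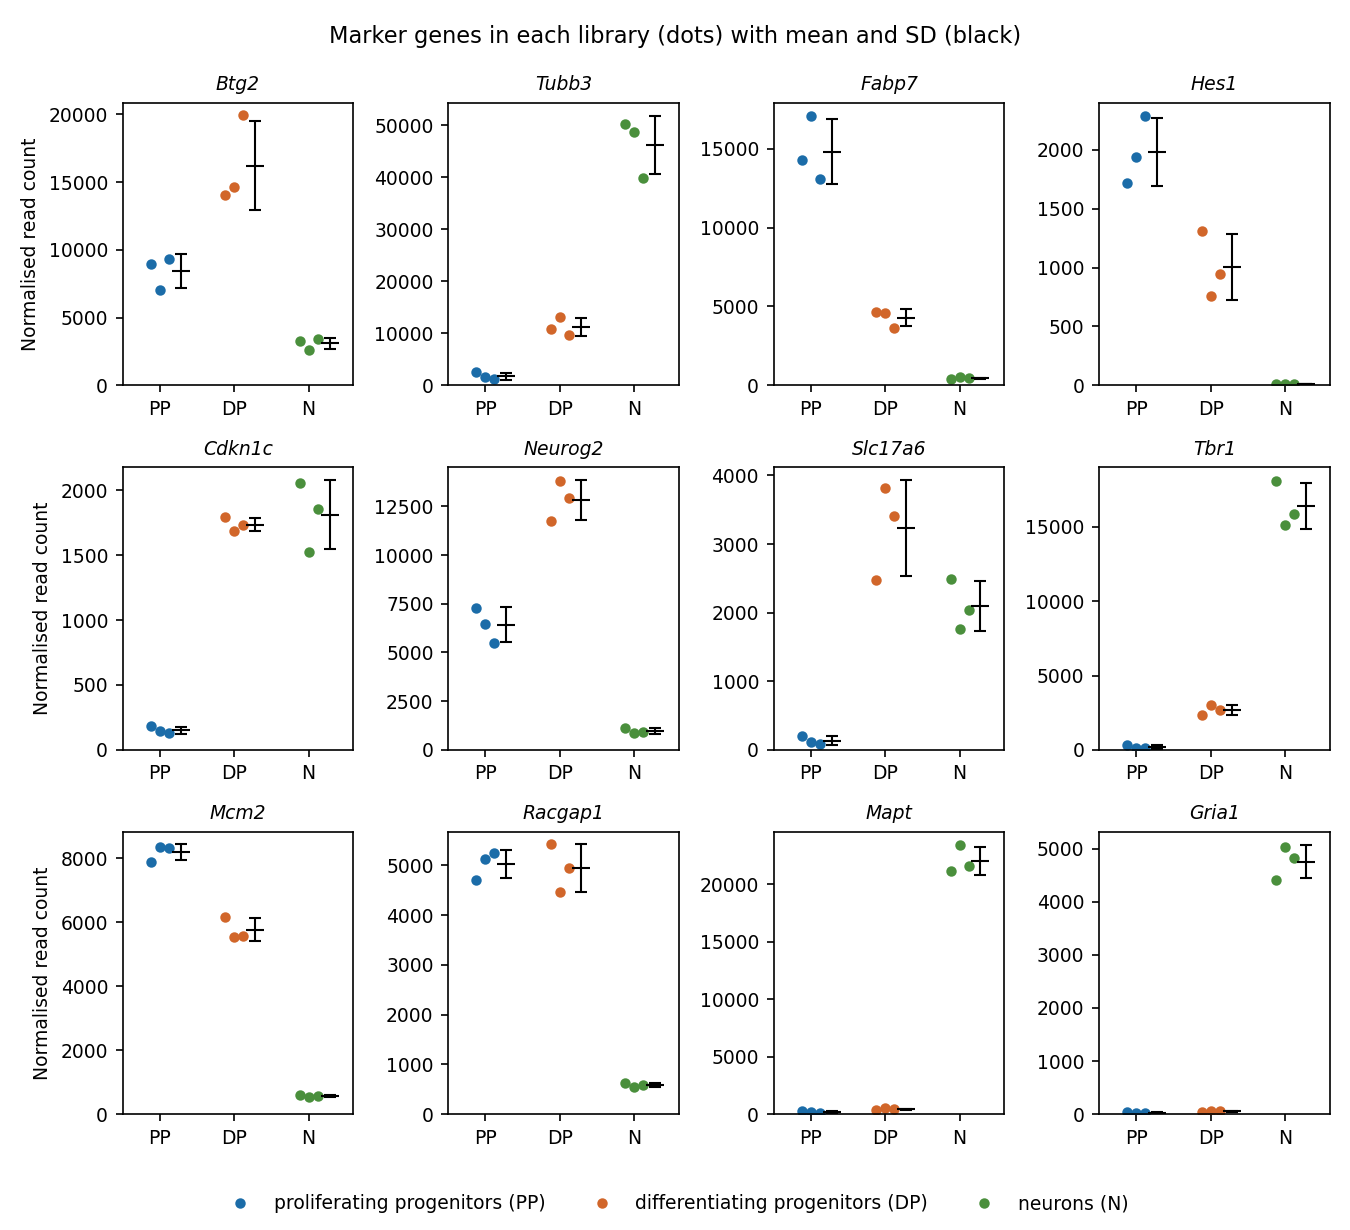
Normalised read counts (vertical axes, from 0) of 12 marker genes in each library, by group, with dots for the 3 libraries and black bars for the mean ± SD. Btg2 and Neurog2 peaked in differentiating progenitors, Fabp7, Hes1 and Mcm2 fell along the lineage, and Tbr1, Mapt and Gria1 were highest in neurons.

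**Figure D2:**
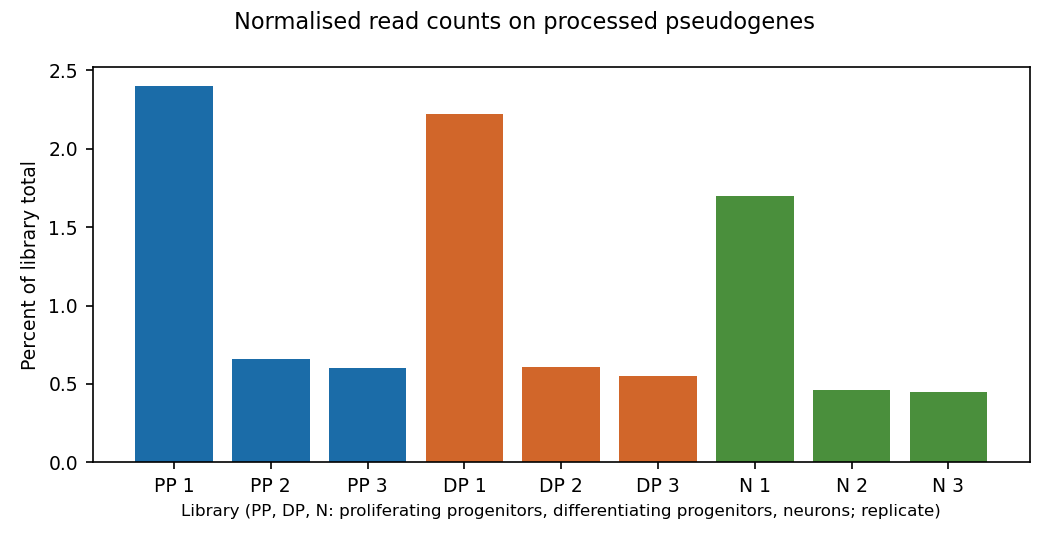
Percent of each library's normalised total that lies on processed pseudogenes (vertical axis, from 0), 1 bar per library, coloured by group. The replicate 1 libraries sit at 2.40%, 2.22% and 1.70%, all above the other 6 libraries, whose highest value is 0.656%.

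Genes named for their large rises from proliferating to differentiating progenitors included transcription factors and a glutamate transporter of young neurons. Most radial glia markers fell, and red blood cell genes were among those with large falls. Nhlh2, a basic helix-loop-helix transcription factor of young neurons, rose from 10.7 ± 5.9 to 428 ± 44.7 (log2 change 5.36 ± 0.39, adjusted p = 3.58e-05). Slc17a6, the vesicular glutamate transporter VGLUT2, rose from 134 ± 66.7 to 3233 ± 693 (log2 change 4.68 ± 0.32, adjusted p = 3.08e-05). St18, a zinc finger factor of the Myt1 family, rose from 41 ± 7 to 1008 ± 193 (log2 change 4.58 ± 0.18, adjusted p = 5.61e-06).

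The comparison asks what separates red from red-negative progenitors, which also held Btg2 transcripts. In limma, 3944 of 15828 genes changed (24.9%), 2186 higher and 1758 lower in differentiating progenitors, and 1041 and 740 of these changed at least 2-fold. With replicate number as a block, 7282 genes changed, 3793 higher and 3489 lower, and all 3944 genes were among them. List members are counted without this block; with it 27 G1/S, 16 cholesterol, 15 endothelial and mural, 7 synaptic, 3 CDK inhibitor and 2 neuron-type BAF genes fell, and 10 interneuron and 6 immediate early genes rose. The block also gave 11 methylation and polycomb genes higher and 8 lower, and 9 known long non-coding RNAs higher and 5 lower. Total-sum scaling, chosen after seeing the data, shifted the log2 changes by -0.07 and turned the balance, with 1880 genes higher and 2254 lower. The lower genes numbered 2651 in replicates 2 and 3 alone, 1060 without proliferating progenitor replicate 2, 1147 without proliferating progenitor replicate 3, 1074 without differentiating progenitor replicate 2 and 1109 without differentiating progenitor replicate 3. Gene lists fixed before the data were examined were tested with camera, which called 20 of 30 at a preset correlation of 0.01. With an estimated correlation camera called 0 of 30, with 11 at an unadjusted p under 0.05, while fry called 23, so each list called below carries both camera p-values.

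**Figure D3:**
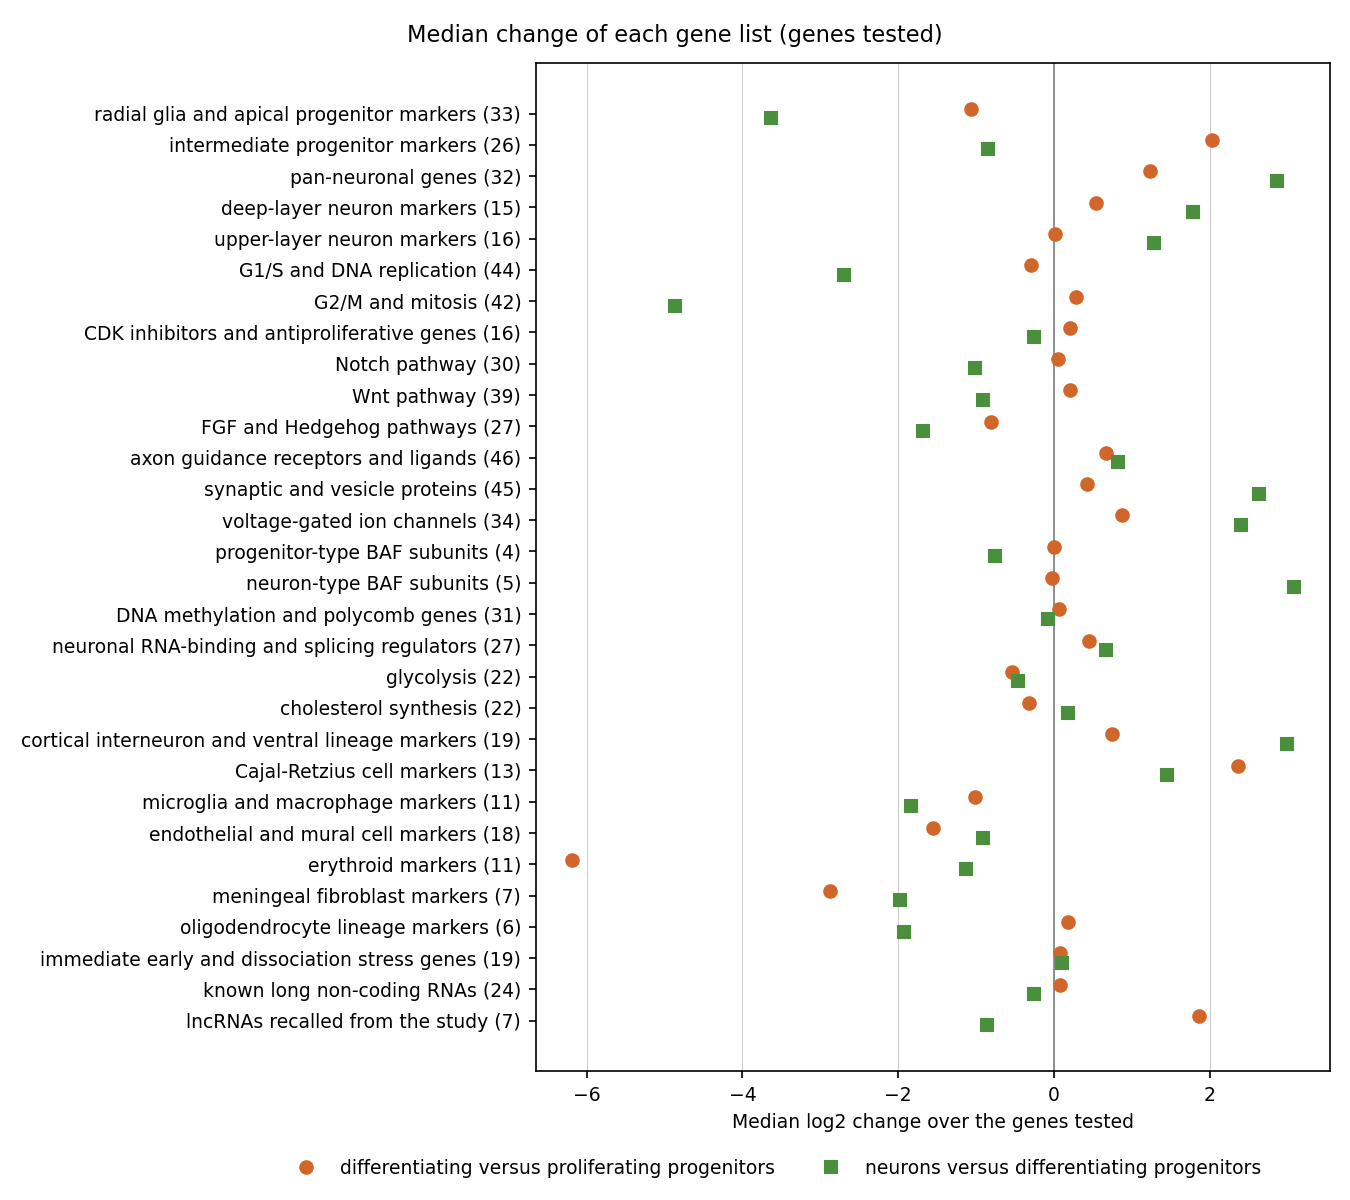
Median log2 change (horizontal axis) over the tested genes of each of 30 gene lists, with the number of genes tested in parentheses, circles for differentiating versus proliferating progenitors and squares for neurons versus differentiating progenitors. Intermediate progenitor markers lie at 2.03 and then at -0.84, G2/M and mitosis genes at 0.28 and then at -4.86, and radial glia markers at -1.06 and then at -3.63.

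Markers of intermediate progenitors, the basal progenitors that divide to make neurons, rose without exception at this step. Of 26 tested, 26 rose and 0 fell (26 and 0 adjusted over the list alone), with a median log2 change of 2.03. Intermediate progenitor markers passed camera with adjusted p = 1.35e-19, against 0.146 with an estimated correlation. Cdkn1c, the cyclin-dependent kinase inhibitor p57, rose from 151 ± 26.8 to 1737 ± 51.3 (log2 change 3.53 ± 0.15, adjusted p = 5.61e-06). Other members that rose were Mfap4 (374 ± 90.8 to 3959 ± 430.1, log2 change 3.42 ± 0.24) and the neuronal RNA-binding protein Elavl4 (1077 ± 231 to 5116 ± 689.6, log2 change 2.26 ± 0.17). Radial glia and apical progenitor markers went the other way: of 33 tested, 0 rose and 25 fell (1 and 28 adjusted over the list alone), with a median of -1.06. Radial glia markers passed camera with adjusted p = 1.77e-14, against 0.165 with an estimated correlation. Fabp7, the brain lipid-binding protein of radial glia, fell from 14809 ± 2045 to 4285 ± 555 (log2 change -1.79 ± 0.13, adjusted p = 3.98e-05). The glutamate transporter Slc1a3 (GLAST) fell from 8269.7 ± 1069 to 2387 ± 611 (log2 change -1.81 ± 0.17, adjusted p = 0.000122). Falls of like size were seen in Ddah1 (9239.7 ± 1435 to 2390 ± 708, log2 change -1.98 ± 0.19) and the chromatin protein Hmga2 (1180 ± 179 to 314 ± 83.4, log2 change -1.93 ± 0.21).

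More neuronal genes had risen than fallen in differentiating progenitors. Of 32 pan-neuronal genes tested, 20 rose and 2 fell (20 and 3 adjusted over the list alone), with a median of 1.24. Pan-neuronal genes passed camera with adjusted p = 8.03e-09, against 0.244 with an estimated correlation. The adhesion molecule L1cam rose from 206 ± 107 to 2976 ± 658 (log2 change 3.94 ± 0.30, adjusted p = 4.79e-05). Snap25, a synaptic fusion protein, rose from 42 ± 14.7 to 446 ± 69.6 (log2 change 3.43 ± 0.27, adjusted p = 5e-05). The adhesion genes Nrcam and Ncam1 fell, Nrcam from 4676 ± 443 to 2800 ± 203 (log2 change -0.74 ± 0.10, adjusted p = 0.000735). Of 46 axon guidance genes, 26 rose and 6 fell (27 and 7 adjusted over the list alone), with a median of 0.67. Axon guidance genes passed camera with adjusted p = 6.81e-07, against 0.164 with an estimated correlation. The netrin receptor Dcc (386 ± 48.4 to 4199 ± 1035, log2 change 3.42 ± 0.16) and the semaphorin co-receptor Nrp2 (96 ± 21 to 1456 ± 295, log2 change 3.91 ± 0.18) rose. Among guidance genes that fell was the semaphorin receptor Plxnc1 (1532 ± 194 to 699 ± 47.5, log2 change -1.13 ± 0.11). Of 45 synaptic and vesicle genes, 25 rose and 3 fell (27 and 4 adjusted over the list alone), with a median of 0.43. Synaptic and vesicle genes passed camera with adjusted p = 2.97e-07, against 0.165 with an estimated correlation. Among those that rose were the vesicular glutamate transporter Slc17a7 (29.3 ± 6.5 to 459 ± 81.9, log2 change 3.93 ± 0.19) and Syn2 (61.3 ± 10.1 to 655 ± 148, log2 change 3.38 ± 0.19). Nlgn3, Gria3 and Grin2b were the 3 that fell, Nlgn3 from 2730.3 ± 149.7 to 1731 ± 264 (log2 change -0.67 ± 0.12, adjusted p = 0.00338). Of 34 voltage-gated ion channel genes, 24 rose and 2 fell (24 and 3 adjusted over the list alone), with a median of 0.88. Ion channel genes passed camera with adjusted p = 4.16e-08, against 0.146 with an estimated correlation. The calcium channel subunit Cacna2d1 (628 ± 38.4 to 3025 ± 928, log2 change 2.22 ± 0.21) rose, and the potassium channel Kcnh7 was among those that fell.

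Layer markers split. Of 15 deep-layer markers 8 rose and 4 fell (8 and 4 adjusted over the list alone), and of 16 upper-layer markers 7 rose and 2 fell (7 and 3 adjusted over the list alone). Camera called neither, with adjusted p = 0.104 for deep layers (0.0317 without proliferating progenitor replicate 1, 0.0485 in replicates 2 and 3 alone) and adjusted p = 0.0641 for upper layers (0.0452 with total-sum scaling). Tbr1, a transcription factor of early-born cortical neurons, rose from 178 ± 122 to 2686 ± 350 (adjusted p = 9.25e-05). Bcl11b rose from 640 ± 268 to 2489 ± 82.4 (log2 change 2.03 ± 0.24, adjusted p = 0.000404), while Ldb2 (183 ± 21 to 57.3 ± 13.2, log2 change -1.68 ± 0.19) fell with Lmo3, Nr4a2 and Etv1. Among upper-layer markers, Mdga1 (2211 ± 103 to 8534 ± 767, log2 change 1.95 ± 0.09) and Unc5d (206 ± 77.5 to 1933 ± 574, log2 change 3.26 ± 0.31) rose. Tox fell from 865 ± 113 to 325 ± 40.4 (log2 change -1.41 ± 0.14, adjusted p = 0.00017), together with Rorb. Cajal-Retzius markers, genes of the earliest cortical neurons, had 13 members tested, of which 12 rose and 1 fell (12 and 1 adjusted over the list alone), with a median of 2.36. Cajal-Retzius markers passed camera with adjusted p = 1.19e-08, against 0.143 with an estimated correlation. Reln, the secreted glycoprotein reelin, rose from 85.3 ± 20.4 to 681 ± 165 (log2 change 2.98 ± 0.21, adjusted p = 3.43e-05). The member that fell was A930038C07Rik, the file's symbol for Ndnf, from 88.7 ± 45.1 to 22 ± 3.5 (log2 change -1.86 ± 0.35, adjusted p = 0.00487). Of 19 interneuron and ventral lineage markers, 3 rose and 1 fell (5 and 1 adjusted over the list alone), with a median of 0.75. Interneuron markers passed camera with adjusted p = 0.0371, against 0.494 with an estimated correlation. Gad2 and Cxcr7 (Ackr3), which rose, and Maf, which fell, passed, but not in every set of 8 libraries, with adjusted p up to 0.0884, 0.0519 and 0.0628. The interneuron call ended without differentiating progenitor replicate 1 (adjusted p = 0.135), proliferating progenitor replicate 2 (0.0818), differentiating progenitor replicate 2 (0.0502) or proliferating progenitor replicate 3 (0.142).

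DNA replication genes fell on balance at this step. Of 44 G1/S and DNA replication genes, 0 rose and 13 fell (0 and 14 adjusted over the list alone), with a median of -0.30. G1/S genes passed camera with adjusted p = 3.95e-06, against 0.285 with an estimated correlation. Ung, a uracil-DNA glycosylase, fell from 1341 ± 80 to 598 ± 70 (log2 change -1.17 ± 0.12, adjusted p = 2e-04). The replicative helicase subunit Mcm2 (8191 ± 252 to 5764 ± 361, log2 change -0.51 ± 0.08) fell with Mcm4. Of 42 G2/M and mitosis genes, 1 rose and 0 fell (0 and 0 adjusted over the list alone), with a median of 0.28. G2/M genes passed camera with adjusted p = 0.0405, against 0.713 with an estimated correlation. The member that rose over all genes tested was the kinesin Kif20b, from 1295 ± 157 to 1707 ± 118 (log2 change 0.40 ± 0.11, adjusted p = 0.0308). Its call ended without any 1 of 4 of the 9 libraries, with adjusted p up to 0.105. The mitotic cyclin Ccnb2 fell without proliferating progenitor replicate 1 (log2 change -0.41, adjusted p = 0.0395) and in replicates 2 and 3 alone (log2 change -0.40, adjusted p = 0.0214). Aurka rose with a replicate block (log2 change 0.53, adjusted p = 0.0155), and Hmmr in replicates 2 and 3 alone (log2 change 0.41, adjusted p = 0.0284), each also without neuron replicate 1 (adjusted p = 0.0346 and 0.0288). The G2/M call ended without proliferating progenitor replicate 1 (adjusted p = 0.507), differentiating progenitor replicate 1 (0.162) or differentiating progenitor replicate 3 (0.0857), with a replicate block (0.0699) and in replicates 2 and 3 alone (0.386). Of 16 genes of CDK inhibitors and antiproliferative factors, 6 rose and 1 fell (7 and 2 adjusted over the list alone), with a median of 0.21. CDK inhibitor genes passed camera with adjusted p = 0.027, against 0.263 with an estimated correlation. The p53-induced genes Trp53inp1 (719 ± 170.3 to 3281 ± 599, log2 change 2.20 ± 0.20) and Sesn1 (800.3 ± 68 to 1712 ± 277, log2 change 1.09 ± 0.12) rose with Cdkn1c, Cdkn1a, Gadd45a and Rb1. The zinc finger gene Plagl1 (14065 ± 1199 to 6835 ± 2010.2, log2 change -1.08 ± 0.18) fell. The CDK inhibitor call ended with a replicate block (adjusted p = 0.051), without differentiating progenitor replicate 1 (0.109) and in replicates 2 and 3 alone (0.0831).

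Signalling lists held genes of both directions. Of 30 Notch pathway genes, 8 rose and 8 fell (8 and 9 adjusted over the list alone). Notch genes did not pass camera (adjusted p = 0.797). The ligands Dll3 (120.3 ± 50.8 to 679 ± 62.2, log2 change 2.56 ± 0.25) and Dll1 (3499 ± 78.1 to 7519 ± 469, log2 change 1.10 ± 0.11) rose with Dll4, Mfng, Numbl, Ncstn and Dtx1. Another ligand, Jag1 (1010 ± 92.4 to 317 ± 16.5, log2 change -1.67 ± 0.15), fell with Notch2, Notch3, Hes1, Hey1, Heyl, Lfng and Dner. Of 39 Wnt pathway genes, 16 rose and 7 fell (18 and 8 adjusted over the list alone), with a median of 0.21. Wnt genes passed camera with adjusted p = 0.029, against 0.347 with an estimated correlation. Wnt5a rose from 51.3 ± 11.4 to 724 ± 65.8 (log2 change 3.81 ± 0.17, adjusted p = 6.05e-06). The Wnt enhancer Rspo3 (26.3 ± 8.4 to 339 ± 59, log2 change 3.66 ± 0.22) rose, and the receptor Fzd8 (5324 ± 368 to 2162 ± 307, log2 change -1.31 ± 0.12) fell. The Wnt call ended with a replicate block (adjusted p = 0.0564), without differentiating progenitor replicate 1 (0.14) and in replicates 2 and 3 alone (0.127). Of 27 FGF and Hedgehog pathway genes, 4 rose and 15 fell (4 and 16 adjusted over the list alone), with a median of -0.81. FGF and Hedgehog genes passed camera with adjusted p = 2.38e-05, against 0.146 with an estimated correlation. The FGF effector Etv5 (1947 ± 223 to 629.7 ± 114, log2 change -1.64 ± 0.15) and Cdon (28369 ± 1699 to 14642 ± 1954, log2 change -0.96 ± 0.11) fell. Among those that rose were Fgf18, Spry1 and Sufu.

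Among glycolysis and cholesterol genes more fell than rose, and among splicing regulators more rose than fell. Of 22 glycolysis genes, 0 rose and 11 fell (0 and 11 adjusted over the list alone), with a median of -0.54. Glycolysis genes passed camera with adjusted p = 8.21e-07, against 0.165 with an estimated correlation. The lactate exporter Slc16a3 (376 ± 56.9 to 109 ± 5.5, log2 change -1.77 ± 0.19) and the glucose transporter Slc2a1 (1884 ± 55 to 1144 ± 8, log2 change -0.72 ± 0.07) fell. Of 22 cholesterol synthesis genes, 1 rose and 9 fell (1 and 15 adjusted over the list alone), with a median of -0.32. Cholesterol genes passed camera with adjusted p = 3.49e-05, against 0.165 with an estimated correlation. The member that rose, Ebp, did not pass without any 1 of 3 libraries, with adjusted p up to 0.0927. Of 27 RNA-binding and splicing regulators, 13 rose and 5 fell (15 and 5 adjusted over the list alone), with a median of 0.45. RNA-binding genes passed camera with adjusted p = 8.63e-05, against 0.221 with an estimated correlation. The splicing activator Srrm4 rose from 1131 ± 383 to 7975 ± 967 (log2 change 2.86 ± 0.20, adjusted p = 3.44e-05). Another regulator, Qk (13246 ± 1210.3 to 6819.7 ± 1155, log2 change -0.97 ± 0.12), fell with Mbnl1, Msi1, Msi2 and Rest, the repressor of neuronal genes. Of 31 DNA methylation and polycomb genes, 5 rose and 4 fell (5 and 4 adjusted over the list alone). Methylation and polycomb genes did not pass camera (adjusted p = 0.797). Jarid2 rose from 1039 ± 37.2 to 1819 ± 215 (log2 change 0.80 ± 0.09, adjusted p = 0.000349), with Tet2, Ezh2, Bmi1 and Phc2. The methyltransferase Dnmt3a (7710 ± 82 to 4674 ± 585, log2 change -0.73 ± 0.10) fell with Uhrf1, Cbx6 and Phc3. Of 4 progenitor-type BAF chromatin remodelling subunits, 0 rose and 1 fell (0 and 1 adjusted over the list alone), namely Phf10. Progenitor-type subunits did not pass camera (adjusted p = 0.808). Phf10 had adjusted p = 0.0694 without proliferating progenitor replicate 2, 0.0536 without differentiating progenitor replicate 2 and 0.0501 without differentiating progenitor replicate 3. Of 5 neuron-type subunits, 2 rose and 0 fell (2 and 0 adjusted over the list alone). Neuron-type subunits did not pass camera (adjusted p = 0.289). Those that rose were Actl6b (18.3 ± 8.5 to 169 ± 65, log2 change 3.14 ± 0.40) and Ss18l1 (723 ± 42.5 to 1386 ± 156, log2 change 0.93 ± 0.11). The neuron-type list had a median of -0.02 but a mean of 0.49, and its test pointed up. With a replicate block Dpf3 (log2 change -1.39, adjusted p = 0.00303) and Smarcd3 (log2 change -0.20, adjusted p = 0.0148) fell, and the progenitor-type Dpf2 rose (log2 change 0.25, adjusted p = 0.00674). Of 19 immediate early and dissociation stress genes, 3 rose and 4 fell (4 and 4 adjusted over the list alone). Immediate early genes did not pass camera (adjusted p = 0.935), with a median of 0.08, a mean of -0.02 and a test that pointed down. Jun fell from 12011 ± 629.6 to 5705 ± 1681 (log2 change -1.11 ± 0.19, adjusted p = 0.00241), with Nr4a1, Klf6 and Cyr61. Its partner Fos (409.7 ± 82.8 to 984 ± 359, log2 change 1.22 ± 0.25) rose with Fosl2 and Ier3.

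More markers of red cells, vessels, microglia and meninges fell than rose. Of 11 erythroid markers, 0 rose and 8 fell (0 and 9 adjusted over the list alone), with a median of -6.19. Erythroid markers passed camera with adjusted p = 3.49e-08, against 0.165 with an estimated correlation. Alas2, the first enzyme of red cell haem synthesis, fell from 4029.7 ± 1162 to 19.7 ± 15 (log2 change -7.80 ± 0.44, adjusted p = 1.42e-05). Hbb-b1, a beta-globin gene, fell from 80544 ± 42266 to 393 ± 495 (log2 change -8.37 ± 0.93, adjusted p = 0.00027). Near-identical globin copies make each globin value uncertain. Of 18 endothelial and mural markers, 0 rose and 8 fell (0 and 13 adjusted over the list alone), with a median of -1.55. Endothelial and mural markers passed camera with adjusted p = 1.45e-05, against 0.296 with an estimated correlation. The pericyte genes Rgs5 (215 ± 101 to 21 ± 16.8, log2 change -3.46 ± 0.55) and Pdgfrb (399 ± 75.8 to 135 ± 13.7, log2 change -1.54 ± 0.26) fell. Of 11 microglia and macrophage markers, 0 rose and 4 fell (0 and 4 adjusted over the list alone), with a median of -1.01. Microglia markers passed camera with adjusted p = 0.00473, against 0.226 with an estimated correlation. Lyz2 fell from 33 ± 7.2 to 1.3 ± 0.6 (log2 change -3.87 ± 0.47, adjusted p = 0.000444), and Csf1r (109 ± 9.1 to 60 ± 6.1, log2 change -0.86 ± 0.18) fell. Laptm5 and Mrc1, the other members that fell, did not pass in every set of 8 libraries, with adjusted p up to 0.121 and 0.0594. The microglia call ended without proliferating progenitor replicate 1 (adjusted p = 0.0719) and in replicates 2 and 3 alone (0.192). Of 7 meningeal fibroblast markers, 0 rose and 4 fell (1 and 4 adjusted over the list alone). Meningeal markers did not pass camera (adjusted p = 0.0956). Igf2 fell from 305 ± 186 to 39 ± 19.2 (log2 change -2.87 ± 0.46, adjusted p = 0.00206). Col1a1, Col1a2 and Col3a1 did not pass in every set of 8 libraries, with adjusted p up to 0.124, 0.0622 and 0.0897. Of 6 oligodendrocyte lineage markers, 1 rose and 1 fell (1 and 1 adjusted over the list alone). Oligodendrocyte lineage markers did not pass camera (adjusted p = 0.935), with a median of 0.18, a mean of -0.02 and a test that pointed down. Cspg4 fell from 136 ± 23 to 48 ± 3.6 (log2 change -1.47 ± 0.23, adjusted p = 0.00189). Mbp, which rose, had adjusted p up to 0.137 with 1 library left out.

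Long non-coding RNAs with the largest rises were A530058N18Rik, from 1 ± 0 to 40.3 ± 8.6 (log2 change 4.35 ± 0.33, adjusted p = 4.61e-05), and A730020E08Rik. A730020E08Rik rose from 8 ± 3.5 to 146 ± 18.2 (log2 change 4.11 ± 0.31, adjusted p = 4.3e-05). Of 24 known long non-coding RNAs tested, 5 rose and 3 fell (5 and 3 adjusted over the list alone). Known long non-coding RNAs did not pass camera (adjusted p = 0.167). A330008L17Rik rose from 14.3 ± 0.6 to 82 ± 15.1 (log2 change 2.42 ± 0.25, adjusted p = 0.000204), with Meg3, Miat, Rmst and 2610307P16Rik. Pvt1 fell from 70.7 ± 7.6 to 31.7 ± 4.9 (log2 change -1.14 ± 0.25, adjusted p = 0.0107), with H19 and Snhg3. Of 7 long non-coding RNAs recalled from the study, 5 rose and 2 fell (5 and 2 adjusted over the list alone), with a median of 1.86. Recalled long non-coding RNAs passed camera with adjusted p = 0.00851, against 0.159 with an estimated correlation. The study chose these on the same samples, as far as recalled, so their direction is not independent evidence. The recalled call ended without differentiating progenitor replicate 1 (adjusted p = 0.0892) and in replicates 2 and 3 alone (0.0706). Miat, a nuclear RNA abundant in neurons, rose from 19611 ± 4673 to 70552 ± 9464 (log2 change 1.86 ± 0.18, adjusted p = 0.000144). Rmst, an RNA of neural progenitors, rose from 118 ± 45.4 to 620.3 ± 71.4 (log2 change 2.45 ± 0.26, adjusted p = 0.000198). Others that rose were 2610307P16Rik (262 ± 32.7 to 797 ± 208, log2 change 1.57 ± 0.21) and Gm16758 (17 ± 6.6 to 114 ± 22.1, log2 change 2.72 ± 0.31). Gm14207 rose from 3 ± 1 to 22.7 ± 4.5 (log2 change 2.58 ± 0.37, adjusted p = 0.00106). C230034O21Rik fell from 175 ± 36 to 90 ± 43.5 (log2 change -1.03 ± 0.32, adjusted p = 0.0447). 9930014A18Rik fell from 92 ± 16.8 to 49.3 ± 19.9 (log2 change -0.95 ± 0.28, adjusted p = 0.0348). Each of these calls ended without any 1 of 7 of the 9 libraries, with adjusted p up to 0.156 for C230034O21Rik and 0.107 for 9930014A18Rik.

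**Figure D4:**
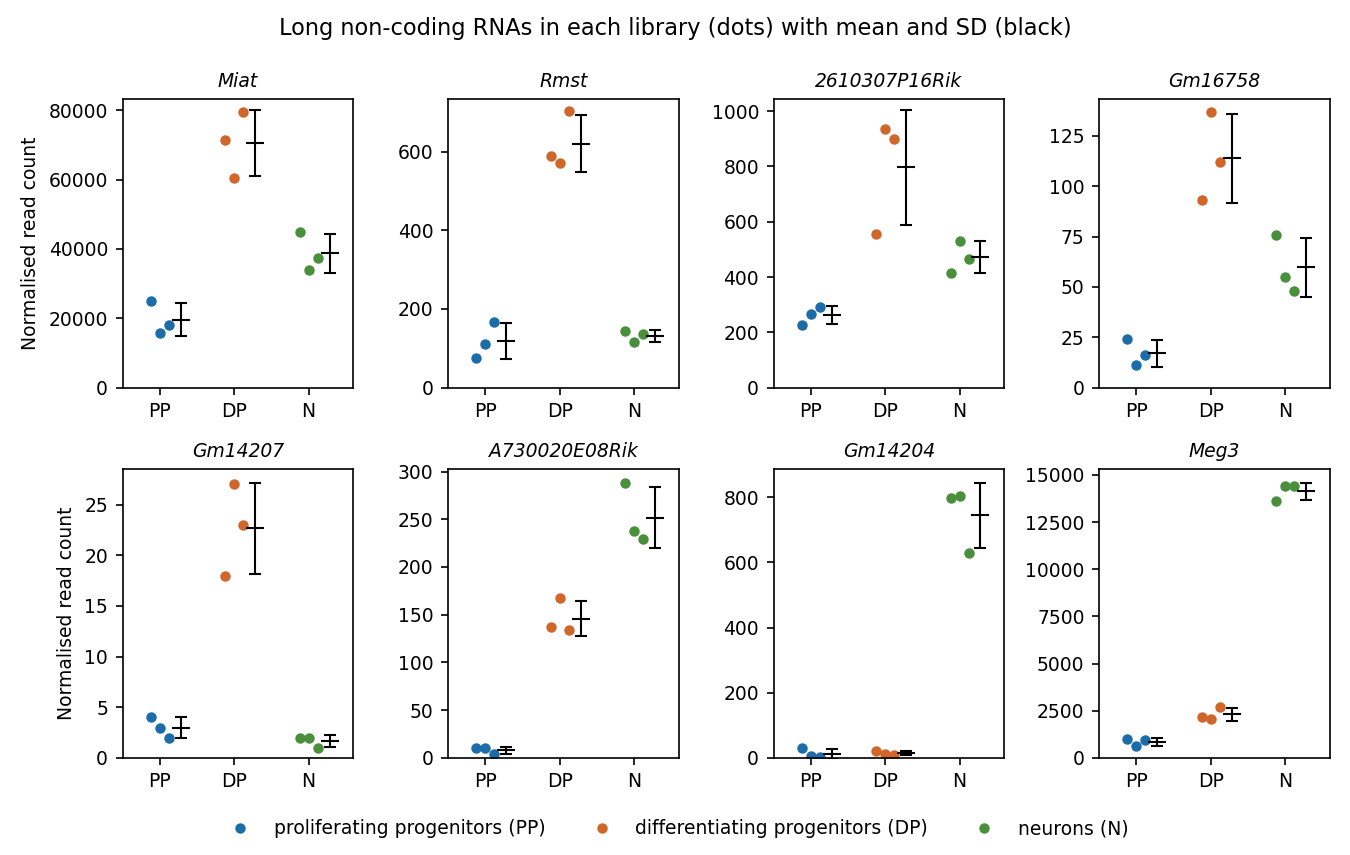
Normalised read counts (vertical axes, from 0) of 8 long non-coding RNAs in each library, by group, with dots for the 3 libraries and black bars for the mean ± SD. Miat, Rmst, 2610307P16Rik, Gm16758 and Gm14207 were highest in differentiating progenitors, and Gm14204 and Meg3 in neurons.

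Most proliferation and progenitor genes of the lists were lower in neurons than in differentiating progenitors. Most synaptic, ion channel and interneuron genes of the lists were higher. Neurog1, a proneural transcription factor, fell from 854 ± 7 to 5.7 ± 3.5 (log2 change -7.17 ± 0.40, adjusted p = 6.36e-07). Lfng, a glycosyltransferase that modifies Notch receptors, fell from 1379 ± 381 to 9.7 ± 2.5 (log2 change -7.01 ± 0.22, adjusted p = 5.4e-08). Grik3, a kainate receptor subunit, rose from 63 ± 13.5 to 9290 ± 521 (log2 change 7.20 ± 0.55, adjusted p = 4.39e-06). Lhx6, a transcription factor of cortical interneurons, rose from 9.3 ± 4.6 to 1644 ± 219 (log2 change 7.44 ± 0.55, adjusted p = 3.71e-06). Sst, a neuropeptide gene, rose from 1.3 ± 0.6 to 546 ± 139 (log2 change 7.87 ± 0.37, adjusted p = 2.76e-07).

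The comparison asks what separates the green neurons from the red differentiating progenitors. In limma, 8551 of 15828 genes changed (54%), 4368 higher and 4183 lower in neurons, and 602 and 801 of these changed at least 8-fold. Scaling libraries to equal totals shifted the log2 changes of this comparison by -0.21 and called 3353 genes higher and 5589 lower, so changes here are relative to the authors' size factors. A replicate block gave 11281 genes, 5661 higher and 5620 lower, and with it 7 erythroid, 8 endothelial and mural and 4 synaptic genes of the lists fell. Camera called 18 of 30 lists, and with an estimated correlation 0 of 30, with 8 at an unadjusted p under 0.05, while fry called 25.

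Every DNA replication and mitosis gene in the lists tested fell. Of 42 G2/M and mitosis genes, 0 rose and 42 fell (0 and 42 adjusted over the list alone), with a median of -4.86. G2/M genes passed camera with adjusted p = 2.34e-22, against 0.183 with an estimated correlation. Of 44 G1/S and DNA replication genes, 0 rose and 44 fell (0 and 44 adjusted over the list alone), with a median of -2.70. G1/S genes passed camera with adjusted p = 1.72e-20, against 0.146 with an estimated correlation. Mcm2 fell from 5764 ± 361 to 575 ± 30 (log2 change -3.32 ± 0.08, adjusted p = 4.22e-08). Of 16 CDK inhibitor and antiproliferative genes, 0 rose and 7 fell (0 and 7 adjusted over the list alone). Among those that fell were the pocket protein Rbl1 (1477 ± 97.1 to 208 ± 44.6, log2 change -2.84 ± 0.15) and the inhibitor Cdkn2c (669 ± 147 to 15.7 ± 10, log2 change -5.51 ± 0.42). Camera gave adjusted p = 0.063 for that list, with 0.0494 under a replicate block, 0.044 without neuron replicate 1, 0.0486 without differentiating progenitor replicate 3 and 0.0353 in replicates 2 and 3 alone. Of 33 radial glia markers, 1 rose and 32 fell (1 and 32 adjusted over the list alone), with a median of -3.63. Radial glia markers passed camera with adjusted p = 1.31e-16, against 0.164 with an estimated correlation. Aldoc, a glycolytic aldolase of radial glia, fell from 4175 ± 906 to 62.3 ± 6.1 (log2 change -6.03 ± 0.17, adjusted p = 4.7e-08). The cadherin Cdh4 (2045 ± 271 to 4899 ± 1305, log2 change 1.23 ± 0.19) was the member that rose. Of 26 intermediate progenitor markers, 3 rose and 15 fell (3 and 16 adjusted over the list alone), with a median of -0.84. Intermediate progenitor markers passed camera with adjusted p = 0.00261, against 0.416 with an estimated correlation. The proneural factor Neurog2 (12844 ± 1022 to 952 ± 144, log2 change -3.76 ± 0.14) and the chromatin remodeller Chd7 (12221 ± 743 to 1985 ± 122, log2 change -2.62 ± 0.08) fell. Mgat4c rose from 3.3 ± 2.5 to 51.3 ± 13.1 (log2 change 3.75 ± 0.48, adjusted p = 0.000136), with Tmem158 and Sox11.

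Among neuronal effector genes far more rose than fell. Of 32 pan-neuronal genes, 31 rose and 0 fell (31 and 0 adjusted over the list alone), with a median of 2.87. Pan-neuronal genes passed camera with adjusted p = 2.92e-14, against 0.165 with an estimated correlation. Mapt, the microtubule protein tau, rose from 438 ± 51.4 to 22055 ± 1212 (log2 change 5.66 ± 0.25, adjusted p = 2.06e-07). Of 45 synaptic and vesicle genes, 40 rose and 1 fell (40 and 2 adjusted over the list alone), with a median of 2.64. Synaptic and vesicle genes passed camera with adjusted p = 9.04e-15, against 0.143 with an estimated correlation. The AMPA receptor subunit Gria1 (52.3 ± 13.1 to 4752 ± 315, log2 change 6.50 ± 0.18) and the scaffold Shank1 (487 ± 36.2 to 9301 ± 196, log2 change 4.26 ± 0.11) rose. The kainate receptor subunit Grik2 (2598 ± 122 to 1714 ± 211, log2 change -0.61 ± 0.12) fell. Of 34 ion channel genes, 33 rose and 0 fell (33 and 0 adjusted over the list alone), with a median of 2.41. Ion channel genes passed camera with adjusted p = 3.38e-12, against 0.143 with an estimated correlation. The calcium channel Cacna1e (129 ± 16.6 to 7413 ± 949, log2 change 5.84 ± 0.15) and the potassium channel Kcna1 (32.7 ± 5.1 to 2313 ± 381, log2 change 6.10 ± 0.26) rose. Of 46 axon guidance genes, 32 rose and 9 fell (32 and 9 adjusted over the list alone), with a median of 0.83. Axon guidance genes passed camera with adjusted p = 0.000147, against 0.213 with an estimated correlation. Of 15 deep-layer markers, 12 rose and 2 fell (12 and 2 adjusted over the list alone), with a median of 1.79. Deep-layer markers passed camera with adjusted p = 0.000296, against 0.146 with an estimated correlation. Ldb2 rose from 57.3 ± 13.2 to 1117 ± 121 (log2 change 4.28 ± 0.19, adjusted p = 1.95e-07), and Nr4a2 and Etv1 fell. Of 16 upper-layer markers, 9 rose and 3 fell (9 and 3 adjusted over the list alone), with a median of 1.29. Upper-layer markers passed camera with adjusted p = 0.0143, against 0.323 with an estimated correlation. Its adjusted p was 0.0712 in replicates 2 and 3 alone. Mef2c rose from 76 ± 5.3 to 3238 ± 346 (log2 change 5.39 ± 0.15, adjusted p = 4.7e-08). Cux1 fell from 3705 ± 330.4 to 1876 ± 279.9 (log2 change -0.99 ± 0.13, adjusted p = 0.000134), with Pou3f2 and Pou3f3.

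Interneuron and Cajal-Retzius markers rose on balance with the neuronal genes. Of 19 interneuron and ventral lineage markers, 12 rose and 3 fell (12 and 4 adjusted over the list alone), with a median of 3.00. Interneuron markers passed camera with adjusted p = 0.00312, against 0.372 with an estimated correlation. Sp8 and Gsx2 were among those that fell. Of 13 Cajal-Retzius markers, 11 rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 1.45. Cajal-Retzius markers passed camera with adjusted p = 0.00557, against 0.206 with an estimated correlation. Ebf2 fell from 142 ± 23.1 to 52.7 ± 7 (log2 change -1.41 ± 0.25, adjusted p = 0.00099). Of 5 neuron-type BAF subunits, 5 rose and 0 fell (5 and 0 adjusted over the list alone), with a median of 3.08. Neuron-type subunits passed camera with adjusted p = 0.00222, against 0.269 with an estimated correlation. The 5 were Dpf1 (572 ± 83.6 to 4836 ± 521, log2 change 3.08 ± 0.13), Actl6b, Dpf3, Ss18l1 and Smarcd3. Of 4 progenitor-type subunits, 0 rose and 3 fell (0 and 3 adjusted over the list alone), with camera adjusted p = 0.0858 and 0.0315 under a replicate block. Ss18 fell from 1934 ± 173 to 979 ± 119 (log2 change -0.98 ± 0.11, adjusted p = 6.69e-05), with Dpf2 and Actl6a. Actl6a had adjusted p = 0.0966 without neuron replicate 1, 0.0989 without differentiating progenitor replicate 2 and 0.101 without differentiating progenitor replicate 3. Of 27 RNA-binding and splicing regulators, 14 rose and 8 fell (15 and 8 adjusted over the list alone). The splicing repressor Ptbp1 (7970 ± 395 to 2902 ± 318, log2 change -1.46 ± 0.09) fell. Camera gave adjusted p = 0.079 for that list, with 0.0473 without neuron replicate 2 and 0.0452 with total-sum scaling. Of 31 DNA methylation and polycomb genes, 8 rose and 12 fell (10 and 13 adjusted over the list alone). Methylation and polycomb genes did not pass camera (adjusted p = 0.456). The polycomb methyltransferase Ezh1 (443 ± 89.6 to 942 ± 52, log2 change 1.11 ± 0.15) rose.

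Of the signalling lists, 30 Notch genes were tested and 6 rose and 20 fell (6 and 20 adjusted over the list alone), with a median of -1.01. Notch genes passed camera with adjusted p = 0.000987, against 0.155 with an estimated correlation. Of 39 Wnt genes, 5 rose and 26 fell (6 and 26 adjusted over the list alone), with a median of -0.91. Wnt genes passed camera with adjusted p = 6.84e-05, against 0.165 with an estimated correlation. Wnt7b rose from 2173 ± 39.9 to 10288 ± 1468 (log2 change 2.23 ± 0.18, adjusted p = 7.41e-06), with Wnt3, Apc, Apc2 and Rspo3. Of 27 FGF and Hedgehog genes, 7 rose and 17 fell (8 and 17 adjusted over the list alone), with a median of -1.68. FGF and Hedgehog genes passed camera with adjusted p = 0.00391, against 0.206 with an estimated correlation. Glycolysis was split: of 22 genes 5 rose and 10 fell (5 and 10 adjusted over the list alone). Glycolysis genes did not pass camera (adjusted p = 0.405). Pfkp, a phosphofructokinase, rose from 126 ± 30.3 to 3103 ± 411 (log2 change 4.63 ± 0.18, adjusted p = 1.25e-07). The neuronal glucose transporter Slc2a3 (255 ± 28.7 to 1052 ± 78.2, log2 change 2.04 ± 0.12) rose with Hk1, Pfkm and Eno2. Of 22 cholesterol synthesis genes, 9 rose and 4 fell (9 and 4 adjusted over the list alone). Cholesterol genes did not pass camera (adjusted p = 0.273). Stard4 fell from 1017 ± 177 to 446 ± 30 (log2 change -1.18 ± 0.12, adjusted p = 3.52e-05), with Idi1 and Insig1. Of 19 immediate early and stress genes, 6 rose and 6 fell (6 and 6 adjusted over the list alone). Immediate early genes did not pass camera (adjusted p = 0.935), with a median of 0.11, a mean of -0.46 and a test that pointed up.

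Most microglia and oligodendrocyte lineage markers were lower in neurons. Of 11 microglia markers, 0 rose and 9 fell (0 and 9 adjusted over the list alone), with a median of -1.83. Microglia markers passed camera with adjusted p = 0.017, against 0.285 with an estimated correlation. With total-sum scaling its adjusted p was 0.0544. Of 6 oligodendrocyte lineage markers, 0 rose and 4 fell (0 and 4 adjusted over the list alone), with a median of -1.92. Oligodendrocyte lineage markers passed camera with adjusted p = 0.0329, against 0.169 with an estimated correlation. Olig2 (114 ± 38 to 3.3 ± 2.5, log2 change -4.86 ± 0.65) and Cspg4 (48 ± 3.6 to 8.7 ± 2.1, log2 change -2.36 ± 0.23) fell with Olig1 and Pdgfra. The oligodendrocyte call ended under a replicate block (adjusted p = 0.0613), without differentiating progenitor replicate 1 (0.0556) and in replicates 2 and 3 alone (0.0732). Camera called none of the endothelial, erythroid and meningeal lists (adjusted p = 0.107, 0.179 and 0.078, the last 0.0451 without differentiating progenitor replicate 2). Of 18 endothelial and mural markers, 1 rose and 4 fell (1 and 4 adjusted over the list alone). Pdgfrb fell from 135 ± 13.7 to 9 ± 3 (log2 change -3.81 ± 0.26, adjusted p = 2.02e-06), with Kdr, Flt1 and Slco1c1. Ets1 rose from 41.7 ± 8.6 to 101 ± 9.2 (log2 change 1.27 ± 0.26, adjusted p = 0.00229). Of 11 erythroid markers, 0 rose and 2 fell (0 and 2 adjusted over the list alone), namely Alas2 and Slc4a1, and both calls ended in limma-voom (adjusted p = 0.165 and 0.0865). Of 7 meningeal markers, 0 rose and 3 fell (0 and 3 adjusted over the list alone). Dcn fell from 62.3 ± 3.5 to 2.7 ± 0.6 (log2 change -4.12 ± 0.37, adjusted p = 1.36e-05), with Ptgds. Col1a2, which fell too, did not pass in every set of 8 libraries, with adjusted p up to 0.0999.

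The long non-coding RNA with the largest rise in neurons was Gm14204, from 14.7 ± 5.7 to 744 ± 98.8 (log2 change 5.62 ± 0.65, adjusted p = 7.19e-05). The one with the largest fall was RP24-273I13.1, from 270 ± 151 to 8.3 ± 4.9 (log2 change -4.84 ± 0.47, adjusted p = 2.22e-05). Of 24 known long non-coding RNAs, 5 rose and 9 fell (5 and 9 adjusted over the list alone). Known long non-coding RNAs did not pass camera (adjusted p = 0.318). Snhg11 rose from 26.7 ± 6 to 644 ± 49 (log2 change 4.56 ± 0.22, adjusted p = 2.73e-07), with Airn, Dlx6os1 and Dlx1as. Meg3, an imprinted gene, rose from 2313 ± 344 to 14142 ± 455 (log2 change 2.62 ± 0.18, adjusted p = 2.22e-06). The imprinted gene H19 (519.7 ± 193 to 67.7 ± 23.2, log2 change -2.92 ± 0.34) fell. The 7 recalled long non-coding RNAs, chosen on these samples and so not independent evidence, all changed against their earlier direction: 2 rose and 5 fell (2 and 5 adjusted over the list alone). Recalled long non-coding RNAs did not pass camera (adjusted p = 0.271). Miat fell from 70552 ± 9464 to 38792 ± 5633 (log2 change -0.86 ± 0.18, adjusted p = 0.0031). Rmst fell from 620.3 ± 71.4 to 131 ± 14.6 (log2 change -2.23 ± 0.26, adjusted p = 6.6e-05). Gm14207 fell from 22.7 ± 4.5 to 1.7 ± 0.6 (log2 change -3.16 ± 0.37, adjusted p = 7.26e-05). 2610307P16Rik fell from 797 ± 208 to 471 ± 57.7 (log2 change -0.73 ± 0.21, adjusted p = 0.0142). Its adjusted p was 0.0565 without differentiating progenitor replicate 2 and 0.0567 without replicate 3. Gm16758 fell from 114 ± 22.1 to 59.7 ± 14.6 (log2 change -0.93 ± 0.31, adjusted p = 0.0305). Its adjusted p was 0.104 without differentiating progenitor replicate 2, 0.0732 without differentiating progenitor replicate 3, 0.085 without neuron replicate 2 and 0.104 without neuron replicate 3. C230034O21Rik (90 ± 43.5 to 210.3 ± 47.2, log2 change 1.29 ± 0.32) and 9930014A18Rik (49.3 ± 19.9 to 203 ± 9.3, log2 change 2.09 ± 0.28) rose.

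Between proliferating progenitors and neurons, the genes named for large rises included receptors and channels, and those named for large falls a globin and an astroglial gene. Gabbr2, a subunit of the GABA-B receptor, rose from 0.3 ± 0.6 to 572 ± 66.3 (log2 change 8.82 ± 0.32, adjusted p = 4.01e-08). Kcnma1, a potassium channel, rose from 0.7 ± 1.2 to 374 ± 93.9 (log2 change 7.99 ± 0.48, adjusted p = 6.63e-07). Mlc1, a membrane protein of astroglia, fell from 1985 ± 121 to 5.3 ± 4 (log2 change -8.58 ± 0.49, adjusted p = 4.37e-07). Hbb-b1 fell from 80544 ± 42266 to 82.3 ± 54.2 (log2 change -10.14 ± 0.93, adjusted p = 1.01e-05). Among long non-coding RNAs, 2900079G21Rik rose from 0.7 ± 0.6 to 251 ± 31.5 (log2 change 7.30 ± 0.61, adjusted p = 5.62e-06). Dlx6os1, an RNA of the ventral forebrain, rose from 34.7 ± 48.2 to 1209 ± 343 (log2 change 6.27 ± 1.12, adjusted p = 0.000889). RP24-273I13.1 fell from 709.7 ± 225 to 8.3 ± 4.9 (log2 change -6.32 ± 0.47, adjusted p = 2.47e-06). Values near 0 make these log2 changes depend on the pseudocount of 1.

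In limma, 10023 of 15828 genes changed (63.3%), 5099 higher and 4924 lower in neurons, and 1000 and 1114 of these changed at least 8-fold. Total-sum scaling shifted the log2 changes by -0.29 and called 3869 genes higher and 6605 lower, and a replicate block 6129 higher and 6245 lower. Camera called 21 of 30 lists, and with an estimated correlation 0 of 30, with 8 at an unadjusted p under 0.05, while fry called 28.

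Over this span the lists of the preceding comparisons added up or cancelled. Of 32 pan-neuronal genes, 31 rose and 0 fell (31 and 0 adjusted over the list alone), with a median of 4.80. Pan-neuronal genes passed camera with adjusted p = 1.49e-14, against 0.165 with an estimated correlation. Mtap2, the file's symbol for Map2, rose from 5522 ± 554 to 41377 ± 3575 (log2 change 2.91 ± 0.10, adjusted p = 3.25e-08). Of 45 synaptic and vesicle genes, 42 rose and 1 fell (42 and 1 adjusted over the list alone), with a median of 3.98. Synaptic and vesicle genes passed camera with adjusted p = 9.91e-16, against 0.143 with an estimated correlation. The member that fell was Syt11 (15913 ± 1970.4 to 9258 ± 1429, log2 change -0.79 ± 0.16). Of 33 radial glia markers, 1 rose and 32 fell (1 and 32 adjusted over the list alone), with a median of -5.01. Radial glia markers passed camera with adjusted p = 5.53e-16, against 0.164 with an estimated correlation. Cdh4 rose from 2928 ± 383 to 4899 ± 1305 (log2 change 0.72 ± 0.19, adjusted p = 0.00908), with adjusted p = 0.0728 under total-sum scaling. Of 42 G2/M and mitosis genes, 0 rose and 42 fell (0 and 42 adjusted over the list alone), with a median of -4.58. G2/M genes passed camera with adjusted p = 2.36e-18, against 0.221 with an estimated correlation. Of 26 intermediate progenitor markers, 16 rose and 6 fell (16 and 6 adjusted over the list alone), with a median of 1.62. Intermediate progenitor markers passed camera with adjusted p = 0.0459, against 0.604 with an estimated correlation. Cdkn1c (151 ± 26.8 to 1814 ± 267, log2 change 3.58 ± 0.15) stayed high. Eomes, Neurog1, Neurog2, Mfng, Neurod4 and Chd7 lay below their level in proliferating progenitors, Neurog2 falling from 6422 ± 897 to 952 ± 144 (log2 change -2.75 ± 0.14, adjusted p = 1.84e-07). The intermediate progenitor call ended without differentiating progenitor replicate 1 (adjusted p = 0.0513), neuron replicate 1 (0.127), proliferating progenitor replicate 2 (0.0634), proliferating progenitor replicate 3 (0.0579) or neuron replicate 3 (0.0568), and in replicates 2 and 3 alone (0.0653).

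Non-neural markers fell too: of 11 erythroid markers 0 rose and 10 fell (0 and 10 adjusted over the list alone). Erythroid markers passed camera with adjusted p = 0.000279, against 0.285 with an estimated correlation. Of 18 endothelial and mural markers 0 rose and 16 fell (1 and 16 adjusted over the list alone). Endothelial and mural markers passed camera with adjusted p = 0.000642, against 0.378 with an estimated correlation. Of 11 microglia markers, 0 rose and 10 fell (0 and 11 adjusted over the list alone). Microglia markers passed camera with adjusted p = 0.00151, against 0.199 with an estimated correlation. Of 7 meningeal markers, 0 rose and 6 fell (0 and 6 adjusted over the list alone). Meningeal markers passed camera with adjusted p = 0.0112, against 0.285 with an estimated correlation. Alas2 stood at 4029.7 ± 1162 in the red-negative gate and 5 ± 1 in neurons. Unlabelled non-neural cells would enter that gate too, and their part in falls from it was not tested.

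Genes that peaked in differentiating progenitors included proneural factors and secreted Wnt pathway ligands. Neurod4, a basic helix-loop-helix factor, stood at 48.3 ± 24, 655 ± 78.1 and 12 ± 10.6 in proliferating progenitors, differentiating progenitors and neurons (log2 change 3.83 ± 0.54 and then -5.97 ± 0.54). Wnt8b stood at 33.3 ± 10, 469 ± 50.8 and 6 ± 1 (log2 change 3.82 ± 0.26 and then -6.08 ± 0.26). Wnt3a stood at 8.3 ± 5.9, 112 ± 7.5 and 1 ± 1 in the same order. Sparcl1, a matrix protein of glia, was among genes lowest in differentiating progenitors, at 451 ± 6.1, 85.3 ± 9.5 and 697 ± 101 (log2 change -2.39 ± 0.14 and then 3.01 ± 0.14). Stac stood at 155 ± 1, 9.3 ± 6 and 42.7 ± 3.1.

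The question is which genes mark the commitment step itself. In limma, 349 genes were highest in differentiating progenitors, passing both comparisons, of which 331 were protein-coding and 16 long non-coding, and 141 exceeded 2-fold in both. With replicate number as a block the count was 779, and it was 525 in replicates 2 and 3 alone, 209 without differentiating progenitor replicate 2 and 216 without differentiating progenitor replicate 3. Another 397 genes were lowest there, 381 protein-coding and 7 long non-coding. That count was 874 with the block, 632 in replicates 2 and 3 alone, 264 without proliferating progenitor replicate 2, 255 without differentiating progenitor replicate 2 and 249 without differentiating progenitor replicate 3. Both comparisons share the differentiating progenitor libraries. Without a group effect hardly any gene passes, so 20 such simulations with 0 genes decide nothing. Their means at an unadjusted p under 0.05 were 62.3 and 84.7. Independent lists of these sizes would share more genes, 578 and 485.

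Gene ontology terms listed in the deposited table were tested in these sets with Fisher's exact test, against the 8633 annotated genes tested. Of 223 annotated genes highest in differentiating progenitors, 17 belonged to pattern specification process against 4.3 expected (adjusted p = 0.00235). Another 13 belonged to Wnt receptor signaling pathway against 2.9 expected (adjusted p = 0.00459) and 8 to heart morphogenesis against 1.2 expected (adjusted p = 0.0161), the next in order of p. Other terms that passed named sensory organ, ear and embryonic organ development, cell fate commitment, somitogenesis and muscle contraction, while neuron differentiation did not pass (adjusted p = 0.0517). In all, 21 of 1784 terms passed for this set. Of 260 annotated genes lowest there, 33 belonged to cell adhesion against 11.5 expected (adjusted p = 3.07e-05), and the 2 terms that passed held the same number of genes.

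Long non-coding genes as a class changed less often than protein-coding genes of like abundance. Between the progenitor groups, 151 of 799 long non-coding genes changed (18.9%), 71 higher and 80 lower, against 27.7% of 13387 protein-coding genes. From differentiating progenitors to neurons 44.2% changed, 133 higher and 220 lower, against 58.9%. From proliferating progenitors to neurons 489 changed (61.2%), 179 higher and 310 lower, against 67.9%. Within deciles of mean expression the exact conditional odds ratios were 0.637 (95% interval 0.524 to 0.772, adjusted p = 3e-06), 0.465 (0.398 to 0.544, adjusted p = 3.14e-22) and 0.630 (0.538 to 0.740, adjusted p = 2.82e-08). For genes highest in differentiating progenitors the odds ratio was 0.718 (0.395 to 1.22, adjusted p = 0.279), and 0.395 with unadjusted p = 0.0359 without differentiating progenitor replicate 3. For genes lowest there it was 0.282 (0.111 to 0.60, adjusted p = 0.00019). That value was 0.102 without proliferating progenitor replicate 1, 0.172 without replicate 3, 0.144 without differentiating progenitor replicate 2 and 0.173 without neuron replicate 2. Replicate 1 deviated in this class too, by median log2 values of 0.23, 0.28 and 0.17 in the 3 groups, which adds spread. In the order of the comparisons the odds ratios were 0.775, 0.524 and 0.633 with a replicate block and 0.713, 0.534 and 0.673 in replicates 2 and 3 alone. The median normalised read count was 31 for long non-coding and 613 for protein-coding genes. The strand setting of the authors' counting is not given in the sources used here, so values of long non-coding genes that overlap another gene, such as antisense genes, could hold reads of that gene.

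The authors' deposited tables hold their own folds and adjusted p-values for the same comparisons. At adjusted p of at most 0.05 they list 2898 genes between the progenitor groups (1617 higher, 1281 lower), 7276 between differentiating progenitors and neurons (3745 higher, 3531 lower) and 9000 between proliferating progenitors and neurons (4557 higher, 4443 lower). Of their genes that passed the filter on low values, limma shared 2750 of 2878 (95.6%), 7104 of 7131 (99.6%) and 8659 of 8674 (99.8%), all in the same direction, and it called 1194, 1447 and 1364 further genes. Across genes, which are not independent replicates, the log2 folds correlated with r = 0.989, 0.994 and 0.995; both sets of folds come from the same libraries.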

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

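Total-sum and upper-quartile scaling, replicates 2 and 3 alone and limma-voom on estimated reads were chosen after seeing the data, the other alternatives before. Where direction was compared, no called gene, list test or odds ratio reversed. Total-sum scaling turned the balance of calls, with 1880 genes higher and 2254 lower between the progenitor groups, 3353 and 5589 from differentiating progenitors to neurons, and 3869 and 6605 from proliferating progenitors to neurons. With replicate number as a block, 7282 genes changed between the progenitor groups instead of 3944, 3793 higher instead of 2186 and 3489 lower instead of 1758. With the block 779 instead of 349 genes were highest in differentiating progenitors and 874 instead of 397 lowest. All 3944 genes stayed among those called, since the block takes out the spread that libraries of equal number share. Replicates 2 and 3 alone gave 2651 lower genes between the progenitor groups, 525 highest and 632 lowest in differentiating progenitors. Leaving out 1 library at a time gave 1060 to 1877 lower genes between the progenitor groups, 209 to 360 highest and 249 to 461 lowest in differentiating progenitors. The odds ratio of long non-coding genes among those highest there then ranged from 0.395 to 0.752, past its threshold without differentiating progenitor replicate 3; the cause was not tested. Among those lowest it ranged from 0.102 to 0.397. The totals of the 3 comparisons ranged from 2642 to 4064, 7301 to 8683 and 8884 to 10202 genes with 1 library left out. With an estimated correlation camera called 0 of the 59 list tests called with the preset one, with 27 of 90 at an unadjusted p under 0.05; fry called 76 and camera with the block 57. Of the tests of lists under other settings, 1218 kept their side of the threshold, 98 lost it and 34 gained it. Among values of named genes 8153 kept their side, 129 lost it and 27 gained it. Alternatives that need raw counts were not run, because reads cannot be recovered exactly from rounded values: DESeq2 size factors, upper-quartile factors in edgeR, the DESeq2 Wald test, a count test on recovered reads and DESeq2 calls for the overlap with the deposited tables. Precision rose with level. The median SE of the log2 change between the progenitor groups was 0.47 in the lowest and 0.12 in the highest decile of mean value. The part of depth in this was not tested.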

Other observations

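Pathway terms listed in the deposited table share some themes with the lists. They were tested with Fisher's exact test among 3389 annotated genes (978 tests, chosen after seeing the data). Genes higher in differentiating than in proliferating progenitors held 45 of 126 axon guidance genes against 17.8 expected (adjusted p = 9.3e-08) and 16 of 39 Hedgehog signalling genes against 5.5 expected (adjusted p = 0.000987), whereas the FGF and Hedgehog list had 4 genes higher and 15 lower; members shared by the 2 sets were not counted. Genes lower there held 50 of 172 focal adhesion genes against 26.1 expected (adjusted p = 6.17e-05) and 25 of 66 genes of extracellular matrix and receptor interaction against 10 expected (adjusted p = 0.000178). Endothelial, mural and erythroid markers were lower in the same comparison, and which cells the matrix and adhesion genes come from was not tested. Genes lower in neurons than in differentiating progenitors held 32 of 35 DNA replication genes against 10.5 expected (adjusted p = 3.51e-11), and genes higher there 67 of 123 calcium signalling genes against 36.8 expected (adjusted p = 1.05e-06).

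The tests of pseudogenes, gene length, depth, carry-over of neurons, neighbouring genes and splits that keep the pairing were chosen after the result was seen, and the other splits before. Of the 10 splits of 6 libraries into 3 and 3, 1 split, the real one, gave as many genes in each comparison, and 10 splits cannot give a share under 0.05. The real values were 3944, 8551 and 10023, and the highest other value in limma was 0, also among the 3 other splits that part as many pairs of equal number. Of 100 drawn splits of the 9 libraries into 3 groups, 4 gave at least 349 genes highest in the middle group and 2 gave at least 397 lowest, the real split included, with 3481 and 3450 as the highest others. Most of these splits mix groups, which adds spread, and ignore the pairing, so they cannot decide on chance. Of 100 splits drawn from the 108 in which every group holds each number once, 6 gave as many highest and 6 as many lowest, with 3911 and 3751 as the highest others. The others that large had all neurons or all proliferating progenitors as the middle group, which points to a structure of the samples: they carry real group differences, so this draw does not decide. The 89 splits with a middle group of mixed origin gave 0 genes in limma, with means of 2.1 and 6.9 at an unadjusted p under 0.05. In the draw without pairing, splits with the replicate 1 libraries as the middle group gave 608 and 605 highest; with replicate number as a block, 779 genes were highest in differentiating progenitors.

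Replicate 1 of every group stood apart from replicates 2 and 3. Over 986 processed pseudogenes the median log2 deviation of replicate 1 was 1.93, 1.94 and 1.88 in proliferating progenitors, differentiating progenitors and neurons, with protein-coding genes at -0.05, -0.04 and -0.05, so reads of expressed genes placed on their pseudogene copies may be a part of it (lowest median 1.88). Loss of reads from parent genes was not seen: 103 protein-coding genes with a pseudogene named after them deviated by a median of 0.03, against -0.04 for other protein-coding genes. Over protein-coding genes, gene length explained 0.63% of the variance of the deviation, so length stays open for pseudogenes. At like estimated reads neuron replicate 1 had 3.07 times the pseudogene share of differentiating progenitor replicate 3, which argues against depth in that pair. Among protein-coding genes with no named pseudogene, libraries of equal number still correlated with r of at least 0.27 across genes, so pseudogene reads are not the whole of it. A difference between batches stays open: the labels name none, but the numbers in the titles run in series per replicate number, with replicate 1 far from the others. No biological explanation was tested.

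Neuronal genes were already higher in differentiating than in proliferating progenitors, which neurons carried over in the sort could cause. Across 144 genes restricted to neurons, differentiating progenitors reached a median of 2.36% of the neuron level. The 10th percentile was 0.26%. With an allowance fixed by the 64-fold cut that defined these genes, it set a limit of 1.85% for an even carry-over of the neuron gate. Over all 1000 genes called at least 8-fold higher in neurons than in proliferating progenitors, chosen without regard to differentiating progenitors, the median was 5.52%, and 4.55%, 6.4% and 5.74% by replicate number, each above that limit. This argues against carry-over as the whole cause; 703 of these genes (70.3%) lay above the limit. Grik3 stood at 0.11%, Gria1 at 0.47% and Mapt at 1.12% of the neuron level, against 15.5% for L1cam and 15.5% for Tbr1. Transcription of neuronal genes in progenitors and young neurons still without green fluorescence both stay open, as untested.

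Long non-coding genes changed with the protein-coding gene that starts beside them on the opposite strand. Across 70 pairs that start on opposite strands at most 1000 bases apart without overlap, log2 changes correlated with r = 0.73, 0.81 and 0.86 in the 3 comparisons, where pairs are not independent replicates (permutation p = 1e-05, the smallest that 100000 permutations can give, and adjusted p = 1.5e-05 over 30 relations). Both genes moved the same way in 34 of 42 pairs called in the last comparison. Its r had a 95% bootstrap interval of 0.77 to 0.91. Overlapping pairs (462) had r = 0.75, 0.79 and 0.82 (protein-coding 0.16, 0.21 and 0.18). Overlap in the authors' gene models was not tested, so shared reads stay open. Across 564 protein-coding pairs of the same arrangement r was 0.15 (0.05 to 0.27), which argues against a change shared by adjacent genes of any kind. Pairs on the same strand had r = 0.40 (0.02 to 0.67) over 34 long non-coding genes upstream and 0.51 (0.15 to 0.78) over 32 downstream, and 0.36 (-0.07 to 0.67) upstream between the progenitor groups. Their median gaps were 9708 and 16311 bases against 135.5, so arrangement and distance differ together, and the difference in r was not tested. For divergent pairs, a shared promoter and regulation of 1 gene by the other were not tested.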
